A study of Homo sapiens with 6 samples.

How the data were processed

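The 6 libraries were analysed, 3 of T24 cells transfected with the control small interfering RNA and 3 with the one against TRAIP; groups and replicate numbers were taken from the sample titles. The sequences of both small interfering RNAs are not given in the sources used here. Per the labels' protocols, RNA was extracted with TRIzol, and libraries were made with a stranded mRNA kit.

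The authors deposited whole-number counts per gene, not normalized. The submitters' processing notes name Trimmomatic 0.36, featureCounts, Subread 1.5.1 and genome build GRCh38; the aligner, the annotation release and the counting options, strand included, are not given in the sources used here. Counts of genes that overlap on opposite strands are therefore treated as uncertain. Among counts from 1 to 10, 70.2% were even, against 50.8% of counts above 1000, a pattern that would arise if both reads of a pair were counted, so a total may be larger than the number of fragments. The authors also deposited RPKM values, which equal the count divided by gene length and by the library's summed gene counts within a relative difference of 1.3e-06. In the gene column, 26 names had been turned into dates by a spreadsheet. Of the 33542 genes, 98.8% matched a gene of GENCODE v29 (GRCh38), from which gene types and exon overlaps were taken; gene positions are those of the deposited table.

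Total gene counts ranged from 39111793 to 70439496 per library, and the common biological coefficient of variation was 5.7%. Between libraries of a group, the chi-square per degree of freedom over genes was 17.4 and 18.0 where siTRAIP replicate 3 was compared, and 3.35 to 7.93 otherwise. Counting both reads of a pair would raise all of these values, not only those with that library. Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts: filterByExpr, TMM factors, a quasi-likelihood fit with robust=TRUE, and the quasi-likelihood F-test of siTRAIP against siNC, 2-sided, with Benjamini-Hochberg adjustment over 18685 genes and a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F. CPM values use TMM-scaled library sizes. Gene lists (35 lists, 708 entries, 688 found in the table) were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset inter-gene correlation of 0.01 and adjustment over the 32 lists with at least 5 tested members. On simulated counts drawn from the means and library sizes of this comparison (18647 genes tested), edgeR called 38.8% of genes changed 1.2-fold, 73.1% of those changed 1.5-fold and 78.1% of those changed 2-fold. Of its 138 calls 13 were false, a share above the threshold of 0.05. The simulation changed 67, 67 and 64 genes at these folds, far fewer than the 2393 called in the data. These shares therefore do not carry over directly.

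The gene lists, the edgeR and camera tests and the rule for naming genes were set before the data were examined; the closing section names the tests chosen later. Named genes are TRAIP and the MYC-MAX network; the 10 largest rises and 10 largest falls among called protein-coding genes with non-overlapping groups and a mean CPM of at least 5; the 5 smallest p-values under the same filters; and up to 4 members of each described list with the smallest adjusted p, plus members that moved against their list. MSMO1, NFKB2, ARHGEF17, E2F1 and E2F8 were named after their values were seen. Some genes that this rule names are not reported here. Alternatives covered DESeq2 1.42.0, other size factors, other count filters, the replicate number as a block, each library left out, limma on log2(RPKM + 0.1) and log2(RPKM + 1), robust=FALSE, a test against a fold change of 1.2, camera with an estimated correlation, and fry. Alternatives chosen after seeing the data were halved counts, removal of GC content and length trends, thinning to equal depth, and leaving out genes that hold leading sequence words.

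For the word search, each 7-base word was regressed on the log2 fold changes of 9230 protein-coding genes with a mean CPM of at least 5 and an annotated 3' UTR of at least 50 bases, with 3' UTR length, GC content and expression as covariates. The transcript with the longest coding sequence stood for each gene, 16063 words present in at least 50 genes were tested, and 100 permutations of the fold changes gave the range expected without a relation. Leading words were also chosen on every other gene, sorted by Ensembl identifier, and tested on the remaining genes. On simulated data a planted shift of -0.15 in genes with a given word was recovered as -0.145, and that word ranked first.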

Results

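RNA sequencing was performed on T24 cells, a human urinary bladder carcinoma line, after transfection with a small interfering RNA against TRAIP (siTRAIP) or a control small interfering RNA (siNC). TRAIP is a RING-type E3 ubiquitin ligase that acts on stalled replication machinery. Each group had 3 libraries, made from total RNA with a stranded mRNA kit. The deposited table held 33542 genes. Total gene counts were 56041110, 54818483 and 58066330 in siNC replicates 1 to 3 and 39111793, 46102683 and 70439496 in siTRAIP replicates 1 to 3. The comparison asks which transcripts change downstream of TRAIP in bladder cancer cells, and the series title ties TRAIP to ubiquitination of MYC.

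TRAIP mRNA (chromosome 3, 49828599 to 49856574, minus strand, GRCh38) fell from 27.8 ± 1.04 CPM in siNC to 12.95 ± 1.61 CPM in siTRAIP (SD, n = 3 each), a fold of 0.465. The log2 fold change was -1.11 (SE 0.07, edgeR adjusted p = 6.74e-10), and the highest siTRAIP library (14.7 CPM) lay below the lowest siNC library (26.6 CPM). MYC mRNA, which encodes the transcription factor named in the series title, stood at 36.9 ± 2.21 CPM in siNC and 34.25 ± 1.165 CPM in siTRAIP (SD, n = 3 each). Its log2 fold change of -0.11 (SE 0.05) did not pass the threshold (edgeR adjusted p = 0.219), and its groups overlapped. The MYC log2 fold change was -0.07 without siNC replicate 2 and -0.17 with limma on log2(RPKM + 0.1), and did not pass in either (adjusted p = 0.611 and 0.0997). Transcript counts measure neither the amount nor the ubiquitination of MYC protein. Among the 10 tested members of the MYC-MAX network, MLX, a MAX-like partner protein, was called. It rose from 96.3 ± 0.804 to 112 ± 1.91 CPM (SD, n = 3 each; edgeR adjusted p = 8.73e-04), although 18.1% of its exonic bases are shared with PSMC3IP on the opposite strand. MGA had a log2 fold change of 0.12 (SE 0.04, edgeR adjusted p = 0.0765). The MAX log2 fold change of 0.25 (SE 0.13, edgeR adjusted p = 0.343) rested on siTRAIP replicate 3, at 82.4 CPM against 62.7 and 60.8 CPM in siTRAIP replicates 1 and 2, and was 0.09 without that library; with the replicate number as a block it was 0.24 and passed (adjusted p = 0.0305).

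**Figure D1:**
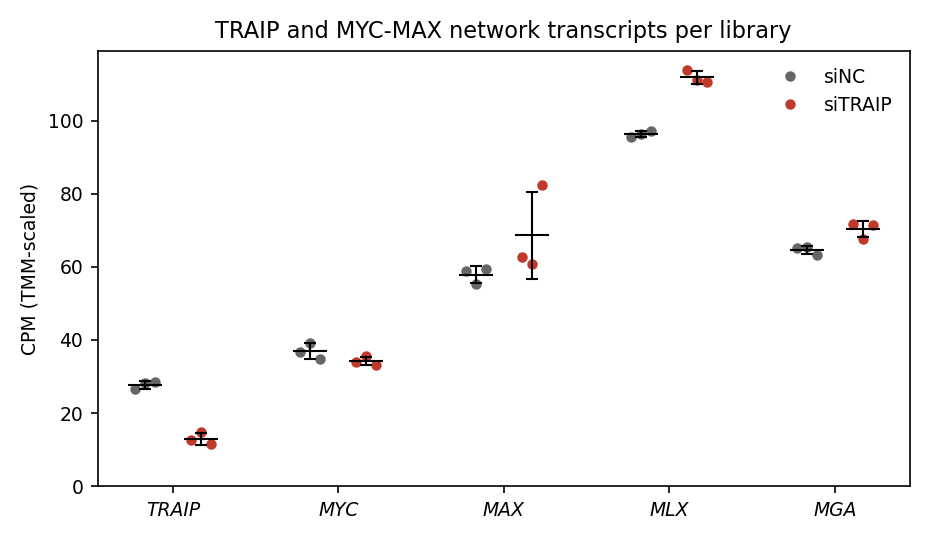
CPM (vertical axis, TMM-scaled) of TRAIP and 4 MYC-MAX network genes in each library; points are the 3 libraries of siNC (grey) and siTRAIP (red), and bars are the mean and SD. TRAIP lies between 11.6 and 14.7 CPM in siTRAIP and between 26.6 and 28.4 CPM in siNC, whereas the MYC values of the groups overlap.

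The largest rises among expressed protein-coding genes were in TPM4, an actin-binding tropomyosin, and HABP4, a hyaluronan- and RNA-binding protein. TPM4 (chromosome 19, 16067021 to 16103005) went from 864 ± 19.6 to 2087 ± 42.6 CPM, a log2 fold change of 1.27 (SE 0.04, edgeR adjusted p = 9.25e-16). HABP4 (chromosome 9, 96450201 to 96491336) went from 82.6 ± 3.22 to 188 ± 2.42 CPM, a log2 fold change of 1.18 (SE 0.04, edgeR adjusted p = 5.33e-15). Other large rises by log2 fold change included ZNF616 (1.06), the arginine methyltransferase PRMT6 (1.05), the heparan sulfate proteoglycan SDC4 (1.03), the cyclin-dependent kinase CDK14 (0.98), the nucleolar phosphoprotein NOLC1 (0.94), the interleukin 6 receptor IL6R (0.93) and the syntaxin STX12 (0.92). The largest fall was in HMGA2, an architectural chromatin protein (chromosome 12, 65824131 to 65966295), from 188 ± 6.21 to 81.85 ± 1.72 CPM, a log2 fold change of -1.20 (SE 0.04, edgeR adjusted p = 5.33e-15). After TRAIP came the fatty acid binding protein gene FABP5 (-0.97), SMIM13 (-0.84), the sterol transfer gene STARD4 (-0.82), REXO1 (-0.82), the growth factor gene HBEGF (-0.80), the lamin B receptor gene LBR (-0.78), FHIP2A, listed under its older name FAM160B1 (-0.76), and the chromatin remodeller subunit MTA2 (-0.74). The values of FABP5 and TPM4 are uncertain because an opposite-strand gene shares 4.5% and 9.6% of their exonic bases and FABP5 has 13 annotated pseudogenes, and CDC14B shares 27.0% of the exonic bases of HABP4. Of the 10 rises, 6 (TPM4, HABP4, ZNF616, PRMT6, CDK14 and NOLC1) held TCGGAGA or CGGAGAA in the coding sequence or 3' UTR, against 18.7% of 9230 genes searched and 33.2% of all called rises among them. Of the 9 falls other than TRAIP, 7 (SMIM13, STARD4, REXO1, HBEGF, LBR, FHIP2A and MTA2) held ACAGTCT or CAGTCTA, against 28.2% and, of all called falls, 44.9%. The words were chosen on fold changes that include these genes.

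Across the transcriptome, 2393 of 18685 tested genes (12.8%) passed an edgeR adjusted p of 0.05, of which 1396 rose and 997 fell. The changes were small: the median absolute log2 fold change of the called genes was 0.262, 87.0% lay under 0.5, and 48 genes changed at least 2-fold, 36 up and 12 down. Groups did not overlap for 29.1% of tested genes, against 10% by chance with 3 libraries a side. Without siNC replicate 1 the count was 1480, and the numbers of genes that rose and genes that fell were 878 and 602, and without siNC replicate 2 the count at least 2-fold was 28. On log2(RPKM + 0.1) with limma, whose scale is the total count, 461 genes rose and 1059 fell, and the count at least 2-fold was 23 there, 17 with DESeq2 and 18 with genes restricted to a CPM of at least 1 in 3 libraries. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so these p-values measure only the spread between these samples, which may be technical.

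Of 22 tested members of the NF-kB and tumour necrosis factor response 12 fell and 1 rose, and adjusted over the list alone 13 fell and 1 rose. The chemokine gene CXCL8 had a log2 fold change of -0.56 (SE 0.04), the cytokine gene LIF one of -0.31 (SE 0.04), the NF-kB feedback inhibitor TNFAIP3 one of -0.29 (SE 0.04) and IL1B, the interleukin 1 beta gene, one of -0.32 (SE 0.05). CXCL1, another chemokine gene, rose instead, by 0.19 (SE 0.05, edgeR adjusted p = 0.00666), a call lost without siNC replicate 2 (adjusted p = 0.0558) and with limma on log2(RPKM + 0.1) (adjusted p = 0.137) or log2(RPKM + 1) (adjusted p = 0.139). The list as a whole was lower (median log2 fold change -0.24, camera adjusted p = 8.53e-07), with adjusted p = 0.0824 with an estimated correlation. Of its 12 falls, NFKB2 alone held ACAGTCT or CAGTCTA, which 28.2% of genes searched and 44.9% of all called falls among them held.

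Of 23 tested genes of cholesterol synthesis and uptake 8 fell and none rose, and adjusted over the list alone 14 fell and 1 rose. STARD4 fell by 0.82 (SE 0.06), IDI1, the isopentenyl diphosphate isomerase gene, by 0.65 (SE 0.06), and FDFT1, the squalene synthase gene, by 0.44 (SE 0.05) on the log2 scale. The list median was -0.20 (camera adjusted p = 8.38e-06), with adjusted p = 0.0689 with an estimated correlation. STARD4, IDI1 and MSMO1 among the 8 falls held ACAGTCT or CAGTCTA, and IDI2-AS1 on the opposite strand shares 14.8% of the exonic bases of IDI1. Of 15 tested YAP and TAZ targets 6 fell and none rose, and adjusted over the list alone 8 fell and 1 rose. DLC1 had a log2 fold change of -0.52 (SE 0.04), the matricellular CCN2 one of -0.33 (SE 0.05) and ANKRD1 one of -0.27 (SE 0.06). Of the 6 falls, DLC1 and ARHGEF17 held ACAGTCT or CAGTCTA, against 44.9% of all called falls searched. The median of this list was -0.12 (camera adjusted p = 0.0123), with adjusted p = 0.167 with an estimated correlation, and without the 5130 genes that held a word of either pair its adjusted p was 0.32.

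Of 25 G1/S and E2F targets 11 rose and 1 fell, and adjusted over the list alone the counts were also 11 and 1. RRM1 and RRM2, the ribonucleotide reductase subunits, rose by log2 fold changes of 0.36 (SE 0.04) and 0.33 (SE 0.04), and RBL1, an RB-family pocket protein gene, by 0.35 (SE 0.05). CCND1, the cyclin D1 gene of the same list, fell by 0.47 (SE 0.04, edgeR adjusted p = 5.14e-08). Overlapping genes share 20.2% of the exonic bases of RRM2, which also has 3 annotated pseudogenes, and 10.3% of those of CCND1, so both values are uncertain. The list median was 0.14 (camera adjusted p = 2.18e-05), with adjusted p = 0.0689 with an estimated correlation. Of 27 replisome and CMG helicase genes 12 rose and none fell, and adjusted over the list alone 13 rose. RFC2, a clamp loader subunit gene, had a log2 fold change of 0.36 (SE 0.05), the helicase gene MCM6 one of 0.32 (SE 0.04), WDHD1 one of 0.31 (SE 0.05) and POLA1, the catalytic subunit of DNA polymerase alpha, one of 0.30 (SE 0.04). The replisome median was 0.14 (camera adjusted p = 2.74e-05), with adjusted p = 0.0689 with an estimated correlation. Of 30 G2/M and mitosis genes 9 rose and 1 fell, and adjusted over the list alone 11 rose and 1 fell. The spindle checkpoint kinase gene BUB1B rose by 0.32 (SE 0.04), the survivin gene BIRC5 by 0.26 (SE 0.04) and CENPF, a kinetochore protein gene, by 0.26 (SE 0.05), whereas CDC20, the activator of the anaphase-promoting complex, fell by 0.21 (SE 0.05); BUB1B-PAK6 shares 10.2% of the exonic bases of BUB1B. The mitotic median was 0.07 (camera adjusted p = 0.00266), with adjusted p = 0.166 with an estimated correlation. TCGGAGA or CGGAGAA was present in 4 of the 11 E2F rises, 5 of the 12 replisome rises (WDHD1 and POLA1 included) and 3 of the 9 mitotic rises (BUB1B, BIRC5 and CENPF), against 18.7% of genes searched and 33.2% of all called rises among them.

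**Figure D2:**
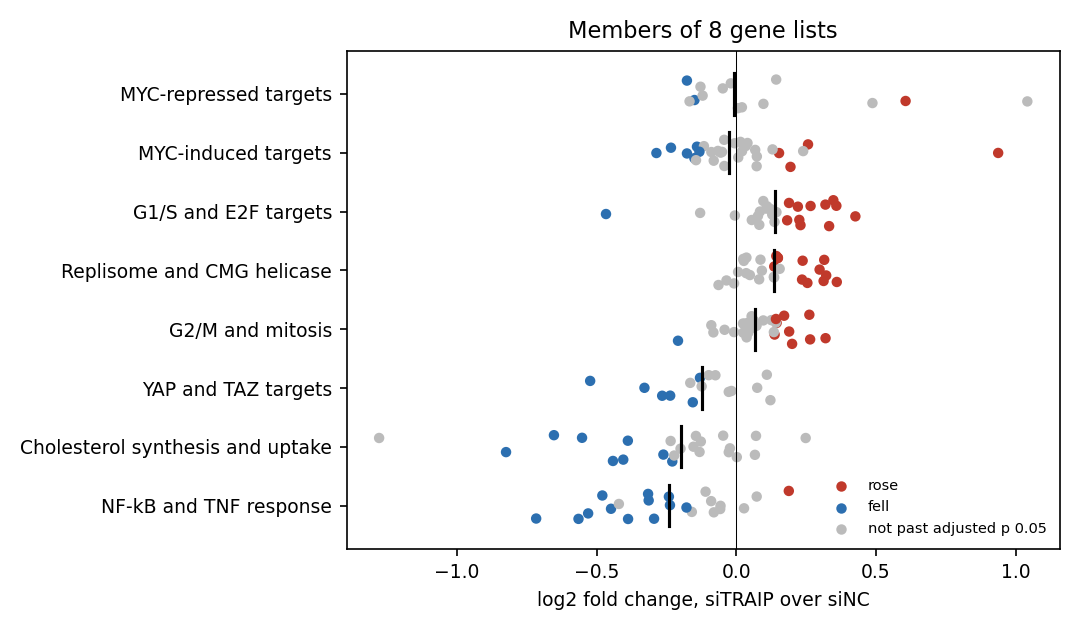
Log2 fold change of siTRAIP over siNC (horizontal axis) for each tested member of the 6 lists called by camera and of both MYC target lists; red points rose and blue points fell at an edgeR adjusted p of 0.05, grey points did not pass, and the black line is the list median. Medians run from -0.24 for the NF-kB and tumour necrosis factor response to 0.14 for G1/S and E2F targets, with both MYC target lists near 0.

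MYC-induced targets went both ways. Of 30 tested members 4 rose and 6 fell, and adjusted over the list alone 5 rose and 8 fell. NOLC1 rose by 0.94 (SE 0.04), while GRWD1, a ribosome assembly gene, fell by 0.29 (SE 0.05) and the mitotic kinase gene PLK1, which shares 11.6% of its exonic bases with an opposite-strand gene, by 0.23 (SE 0.04) on the log2 scale. The list was not called by camera (adjusted p = 0.714): its median log2 fold change was -0.02 and its mean 0.01, and the direction of the test was down. Of 14 tested MYC-repressed targets 1 rose and 2 fell, both over all genes and adjusted over the list alone, with a camera adjusted p of 0.98, a median of -0.01, a mean of 0.11 and a test direction of down. NDRG1, a metastasis suppressor gene, rose by 0.61 (SE 0.06, edgeR adjusted p = 1.27e-07). CDKN1B and GADD45A fell (edgeR adjusted p = 0.0297 and 0.0388). The call on the CDKN1B log2 fold change was lost without siNC replicate 2 (adjusted p = 0.191) or 3 (0.05) and without siTRAIP replicate 1 (0.0932) or 2 (0.0716). That on the GADD45A log2 fold change was lost without any single library other than siTRAIP replicate 3, with adjusted p from 0.0777 to 0.207, on both RPKM scales (0.058 and 0.0609) with GC content and length trends removed (0.0557) and with the replicate number as a block (0.054).

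Of the 32 lists with at least 5 tested members, 6 passed a camera adjusted p of 0.05 and none with an estimated correlation, while fry, which asks only whether members move on balance one way, called 11. The estimated correlation lay below the preset one for the cholesterol, E2F, replisome and YAP and TAZ lists. A higher correlation therefore does not account for the loss of these calls. Of the markers of other cell types, no endothelial one, the leukocyte marker CD68 and the fibroblast markers PDGFRB and COL6A2 passed the expression filter. CD68, a lysosomal glycoprotein gene, rose from 34.9 to 43.3 CPM, a log2 fold change of 0.31 (SE 0.06, edgeR adjusted p = 9.17e-04), although AC016876.2 shares 81.7% of its exonic bases. COL6A2 stood at 122.1 CPM in siNC and 119.6 CPM in siTRAIP, and neither it nor PDGFRB passed the test (edgeR adjusted p = 0.723 and 0.957).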

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

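The halved counts, the GC content and length correction, the thinning and the removal of word genes were chosen after seeing the data. For the TRAIP knockdown, the log2 fold change lay between -1.21 and -0.99 and passed the threshold in every alternative run for it. Of 2589 values of named genes under alternatives, 2371 stayed on the same side of the threshold, 190 lost the call and 28 gained it. None of 1915 values of called genes changed sign, and 16 of 674 values of genes not called did, in 7 genes. With 1 library left out, the counts ran from 1480 to 2622 genes changed, 878 to 1471 genes that rose, 602 to 1151 genes that fell and 28 to 55 at least 2-fold, with fewer samples in each fit. Changes of at least 2-fold numbered 17 with DESeq2, for which the cause was not tested, and 18 with a CPM of at least 1 in 3 libraries, which tests 14480 genes. With limma on log2(RPKM + 0.1), 1520 genes changed, 461 rose and 23 reached 2-fold; with log2(RPKM + 1), 1519, 450 and 7. On these scales the median log2 fold change of all genes was -0.06 and -0.03, and 1238 and 1226 of the calls were shared. The RPKM values do not use the TMM factors, which were 1.011 to 1.029 in siNC and 0.971 to 0.987 in siTRAIP. Leaving these factors out sets siTRAIP lower than in the main fit, the direction of both medians. How much this adds to the lost calls was not tested. The test against a 1.2-fold change, by construction stricter, called 217 genes (130 rose, 87 fell, 20 at least 2-fold). Without word genes, 13555 genes were tested and 1204 changed (743 rose, 461 fell, 24 at least 2-fold). Equal depth gave 2251 genes.

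Camera with an estimated correlation called 0 lists of 32, of which 6 passed with the preset one, and fry called 11. With the estimated correlation the adjusted p was 0.0689 for the cholesterol, E2F and replisome lists, 0.0824 for NF-kB, 0.166 for G2/M and 0.167 for YAP and TAZ. Over 17 other alternatives it ran from 4.01e-10 to 2.04e-05 for NF-kB, 8.41e-10 to 8.26e-05 for cholesterol, 5.57e-06 to 3.98e-04 for E2F, 5.67e-07 to 8.47e-04 for the replisome, 3.41e-04 to 0.0453 for G2/M and 5.62e-04 to 0.0371 for YAP and TAZ. Without word genes, which leaves fewer members, it was 1.42e-05 for NF-kB, 9.49e-04 for cholesterol and for E2F, 0.00218 for the replisome, 0.0297 for G2/M and 0.32 for YAP and TAZ (10 of 15 members).

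The sample titles do not say whether equal replicate numbers mark paired libraries, and the values showed no sign of it. Deviations of same-numbered libraries correlated at -0.01, -0.02 and 0.001, and no library correlated best with its own number. This cannot exclude that they were prepared in pairs. With the number as a replicate block, 2145 genes were called, with 1279 genes that rose, 866 genes that fell and 39 at least 2-fold. The TRAIP log2 fold change was -1.11 and 7 lists passed in that fit, against 6 in the main fit. There the MAX log2 fold change passed (0.24, adjusted p = 0.0305) and the GADD45A log2 fold change did not (-0.15, adjusted p = 0.054).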

Other observations

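The test of match length in genes not used to choose the words was chosen after the word result was seen; the limit used in the MYC-induced list test was changed from the SD over libraries to the SD over members after its value was seen, and under the earlier limit that value would have argued against MYC-driven transcription; the YAP list test was added after its result was seen, and the removal of word genes and of GC content trends was added after seeing the data.

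Single members of lists that camera did not call also moved. In the ATF4 and amino acid response (2 rose and 5 fell of 21 tested, camera adjusted p = 0.855, fry adjusted p = 0.0235, down), the cystine transporter gene SLC7A11 and the leucine transporter gene SLC7A5 each had a log2 fold change of -0.38 (SE 0.04 and 0.05, edgeR). The median of that list was 0.02, its mean was -0.02 and both tests pointed down. Among matrix proteases (0 rose and 2 fell of 13, camera adjusted p = 0.57, fry adjusted p = 0.00596, down), ADAMTS1 and the urokinase gene PLAU each had one of -0.41 (SE 0.04 and 0.05, edgeR), although C10orf55 on the opposite strand shares 31.1% of the exonic bases of PLAU. DDIT4, an inhibitor of mTORC1 signalling, rose by 0.59 (SE 0.06) within a hypoxia list with 1 rise and 2 falls of 14 (camera adjusted p = 0.714, fry adjusted p = 0.411), and DDIT4-AS1 shares 41.2% of its exonic bases.

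Library siTRAIP replicate 3, the deepest, stood apart in some genes. MT-ND6, singled out after its values were seen, was at 2283 CPM there and between 463 and 687 CPM in the other 5 libraries. The mean shift of 9 replication-dependent histone genes was -0.55 there, against -0.11 and -0.15 in siTRAIP replicates 1 and 2. Some of these genes had few counts. In siTRAIP replicates 1 to 3, H2BC4 had 8, 6 and 4, whereas H2AC6 had 92, 100 and 133. A few reads can therefore move this mean. Leaving out siTRAIP replicate 3 gave 2622 called genes in place of 2393.

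Sequence words were more frequent among called genes than among others: 44.9% of 809 called falls searched held ACAGTCT or CAGTCTA against 26.6% of the others, and 33.2% of 1118 called rises held TCGGAGA or CGGAGAA against 16.7%. These words were chosen on the same fold changes, so the shares are not a separate test. They are also not adjusted for sequence length. The leading word of the falls, ACAGTCT in 3' UTRs of 1112 genes, had t = -12.1 (range of 100 permutations -4.81 to 5.13), and that of the rises, TCGGAGA in 170 genes, had t = 11.2, with 3' UTR length, GC content and expression in the model, which argues against those properties as the whole cause. With the words chosen on every other gene, which gave ACAGTCT and TCGGAGA again, the mean log2 fold change of the remaining genes was 0.014 with the 6-base core alone and -0.079 with the 8-base ACAGTCTA (101 genes), a difference of -0.09 (SE 0.02), and 0.028 and 0.196 for the core and all 8 bases of TCGGAGAA (24 genes), a difference of 0.17 (SE 0.04). ACAGTCTA lies in TRAIP itself (chromosome 3, 49840360 to 49840367, minus strand, GRCh38), in 5 of 11 transcripts and within the coding sequence of 4 of them, where 4.7% of all 8-base words occur in some TRAIP transcript, and TCGGAGAA lies in none. A candidate explanation, as a hypothesis, is seed pairing: of the duplex against TRAIP for the falls, and of the control duplex, acting in siNC, for the rises; the limit set beforehand, a coding-sequence shift under 0.5 of that in the 3' UTR, was missed (-0.037 against -0.069, and 0.074 against 0.145 with t = 11.6 in the coding sequence), the word ranked next for the rises, GGAGAAA (t = 9.4), had 0.038 against 0.045 and occurs in 7 TRAIP transcripts, the duplex sequences are not given in the sources used here, and no biological explanation was tested.

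The 6 called lists were tested for the words as well. Without genes that held any of the 4 leading words, 6 of the 6 lists kept at least 0.5 of their mean shift. For their own members, this argues against matches to these 4 words as the whole cause. Genes with other words past the permutation range, such as GGAGAAA (t = 9.4) and CAGTCTT (t = -7.0), were not removed for those words. Matches to such words therefore stay open for all 6 lists. The removal cannot test effects passed on from a gene with a word to members without one. E2F1 and E2F8 among the E2F rises and NFKB2 among the NF-kB falls held a word of their direction. The YAP and TAZ list went from -0.12 (SD over libraries 0.01, 15 members) to -0.07 (value -0.071, SD 0.01, 10 members). It was no longer called, with fewer members and a smaller shift, so word matches stay open for that list. With GC content and length trends removed, again 6 lists kept at least 0.5 of their mean shift, which argues against those trends. Higher MYC-driven transcription cannot be told apart from its absence by the test set here. The MYC-induced list had a mean shift of 0.014 with members going both ways (SD 0.22), among them NOLC1 at 0.94, which held a word. With that SD over members as the limit, only a clearly negative mean could have argued against higher MYC-driven transcription. In siTRAIP replicates 1 to 3 the mean shift of the list was 0.017, 0.024 and 0, so as a set it showed no clear rise. An effect of TRAIP loss itself stays open and was not tested against another duplex.

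The 6 libraries allow 10 splits of 3 against 3, too few for a share under 0.05; the real split gave 2393 genes, 1 of the 10 splits gave as many, and the highest of the others gave 0.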
